A study of Mus musculus with 6 samples.

How the data were processed

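Total RNA from mouse material labelled lung tissue was made into libraries with a kit for messenger RNA, per the labels' protocols, and 6 libraries were analysed, 3 labelled Aalter and 3 labelled VE. The deposited table holds estimated counts per gene and library, per the file headers, which need not be whole numbers, and between 10.5% and 12.2% of the values in a library were not whole. The values were not scaled, since library totals differ. The submitters' processing notes name the genome build mm10, and the aligner, the counter and its strand setting are not given in the sources used here. The table lists 21956 Ensembl gene IDs, of which 4236 had 0 in every library and 83 had no symbol and stayed without a name. GENCODE vM21, used for coordinates, gene types, GC content and transcript length, held 21804 of the IDs and lacked 152 (0.692%). In 1 row an extra cell held a stray value, which was left out.

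Columns were matched to samples by name and replicate number. Counts were rounded to whole numbers. The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr on the groups, robust quasi-likelihood fits and Benjamini-Hochberg adjustment, on all 6 libraries with the group as the only term and a threshold of 0.05. Fold changes are VE relative to Aalter. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. CPM are edgeR's normalised read counts, relative to library size times the TMM factor, given as mean ± SD over 3 libraries, except for S100a9, Ptprc, Sftpc, Ager and the trace and Y-linked genes, where library size alone was used. A gene is said to have risen or fallen where it passed this test. The common biological coefficient of variation was 0.210. A count of 3, the limit that a count of 0 allows, is between 0.185 and 0.258 CPM in these libraries, which covers counting error only.

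Before the data were examined, 44 gene lists were fixed, for type 2 inflammation, ILC2, ferroptosis, NRF2 targets, LKB1 and AMPK, vitamin E, metabolism, inflammation, stress, and markers of lung and neighbouring cell types. Of these, 42 had at least 3 measured members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with adjustment over the lists. Of the 42 lists 12 passed, 7 upward and 5 downward, and 0 passed with an estimated correlation. The rotation test fry, which asks whether members move on balance in 1 direction without comparing them with other genes, passed 14 lists. Of the 12 lists, those of interferon response, plasma cells, interstitial macrophages and monocytes, club cells and alveolar macrophages did not pass fry (adjusted p from 0.0617 to 0.0925). Lists such as ILC2 markers, ferroptosis defence, lipid synthesis, natural killer cells and dendritic cells passed fry but not camera. Lists other than the 12 did not pass camera with the preset correlation.

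Named genes were chosen by a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among genes past the test, with groups that do not overlap and a mean of at least 1 CPM, leaving out unnamed models, pseudogenes, ribosomal protein genes and antigen receptor segments. It adds Il5, Il13, Il4, Il33, Il1rl1, Gata3, Muc5ac, Ccl11, Gpx4, Slc7a11, Acsl4 and Stk11 whatever their values, up to 4 members with the smallest p of each list that passed camera and up to 2 of each other list. Some genes that the rule takes are not reported here. Counts in antigen receptor, haemoglobin and other multigene families could be split between copies by the counting.

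No pair of libraries agreed within sampling noise, with a median chi-square per gene of at least 0.707 against 0.455 for noise alone, so none was taken for a copy of another. This covers counting error only, and repeat libraries of 1 sample could differ as much, so it does not show that the 6 are separate replicates. On simulated data with the real means and library sizes, 98 genes changed by 1 on the log2 scale were recovered in 52.0% of cases and 96 genes changed by 2 in 91.7%, over 12551 genes, and 9.15% of calls were false. Alternatives were RLE and library-size scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean of at least 5 CPM, a fold change of at least 2, a replicate block, and each library left out in turn. Added after seeing the data were fits without Aalter-1 and VE-1, without immunoglobulin genes, and with each library's trends on GC content and on the length of the longest transcript removed as offsets, from splines with 5 degrees of freedom over the 99.8% of tested genes with both values. Quantities were computed with Python 3.11.15, and figures drawn with matplotlib 3.10.9.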

Results

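Gene expression was measured by RNA sequencing in mouse material that the labels call lung tissue. The labels give 2 groups, Aalter and VE, with 3 libraries each, and they do not spell out either name. The title of the series names alpha tocopherol, a form of vitamin E, allergic airway inflammation, the death by lipid peroxidation called ferroptosis, group 2 innate lymphoid cells (ILC2, lymphocytes without antigen receptors that secrete type 2 cytokines) and the kinase LKB1. The comparison therefore asks how transcripts of the VE group differ from those of the Aalter group. No untreated group was analysed here. Total estimated counts were 15189598, 11617074 and 16205053 in Aalter-1, Aalter-2 and Aalter-3, and 14744185, 12663763 and 15077851 in VE-1, VE-2 and VE-3. Nothing in the labels says that the libraries come from separate animals, so p-values measure the spread between these samples, which may be technical.

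Leukocyte transcripts were abundant in all 6 libraries, as read from genes chosen after their values were seen. The neutrophil gene S100a9 lay between 12054 and 19515 CPM and the pan-leukocyte gene Ptprc between 1128 and 1489 CPM. The alveolar type 2 gene Sftpc lay between 12.6 and 17.7 CPM and the alveolar type 1 gene Ager between 1.98 and 6.001 CPM. The surfactant genes Sftpa1, Sftpb and Sftpd, abundant in whole lung, were low as well. They averaged 10.4, 6.12 and 5.92 CPM in Aalter and 7.16, 6.03 and 6.48 CPM in VE. Napsa was the highest of 12 measured type 2 markers, at 102 and 135 CPM. The labels describe no isolation of cells, yet these values argue against whole lung in its usual make-up and go with material rich in leukocytes. How this arose was not tested. Values of epithelial and airway genes may thus come from a small part of the material. The first principal component held 66.7% of the variance. It set VE, with scores of 36.01 to 40.2, apart from Aalter-2 and Aalter-3 at -61.4 and -56.0. Aalter-1 stood between them at 2.34, nearer to VE. Its log2 CPM had Pearson correlations of 0.973 to 0.983 with the VE libraries and of 0.962 and 0.965 with Aalter-2 and Aalter-3.

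**Figure D1:**
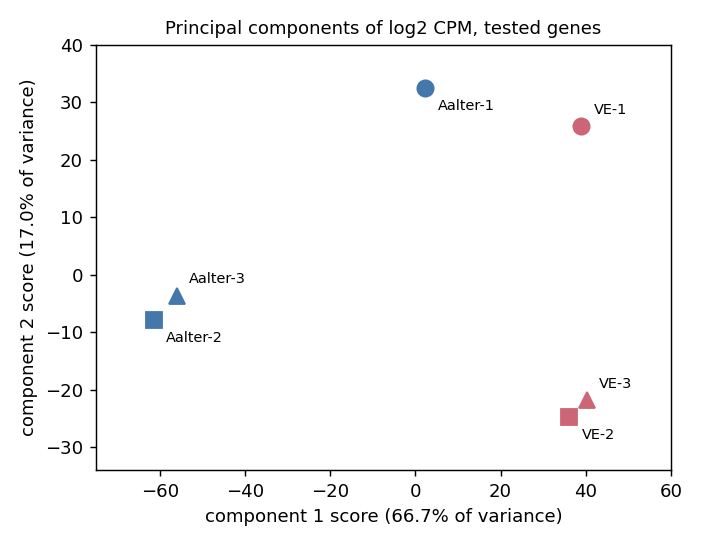
Scores of the 6 libraries on the first and second principal components of log2 CPM over the tested genes. Blue marks Aalter, red marks VE, and the shape gives the library's number. Aalter-1 lies at 2.34 on the first component, between Aalter-2 and Aalter-3 at -61.4 and -56.0 and the VE libraries at 36.01 to 40.2.

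The type 2 cytokine genes Il5 and Il13 and the transcription factor gene Gata3, which directs type 2 lymphocytes, were lower in VE. Il5 averaged 3.94 ± 1.89 CPM in Aalter and 0.480 ± 0.167 CPM in VE (SD, n = 3), a log2 fold change of -3.03 ± 0.51 (SE) with an adjusted p of 0.00939. Il13 fell from 5.72 ± 2.94 to 1.27 ± 0.375 CPM, with a log2 fold change of -2.16 ± 0.48 and an adjusted p of 0.0183. Gata3 fell from 21.3 ± 5.63 to 5.99 ± 1.09 CPM, with a log2 fold change of -1.83 ± 0.24 and an adjusted p of 0.00559. These p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as are all adjusted p-values of single genes below. In GENCODE vM21 (mm10), Il5 (ENSMUSG00000036117) lies on chromosome 11 from 53720794 to 53725106, Il13 (ENSMUSG00000020383) on chromosome 11 from 53631324 to 53634702 and Gata3 (ENSMUSG00000015619) on chromosome 2 from 9857078 to 9890034. All are protein-coding genes, and the counts are given per gene. In Aalter-1 these genes lay between the other Aalter libraries and VE, with Il5 at 1.77 CPM against 4.84 and 5.21 CPM in Aalter-2 and Aalter-3.

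Il4 did not pass (log2 fold change 0.67 ± 0.34, adjusted p = 0.161), nor did the alarmin gene Il33 (0.16 ± 0.20, adjusted p = 0.549) or its receptor gene Il1rl1 (-0.10 ± 0.14, adjusted p = 0.606). The eosinophil chemokine gene Ccl11 did not pass either (1.26 ± 0.56, adjusted p = 0.118), though it passed without Aalter-1 (1.78, adjusted p = 0.0291), and its adjusted p over all alternatives reached 0.303. Muc5ac, a mucin of airway goblet cells, had too few counts to test, with 5, 17 and 12 in Aalter and 0, 0 and 2 in VE. Of the 8 measured members of the type 2 cytokine list, 3 rose and 2 fell, and the same numbers came out when adjusted over the list alone. The risers were Il6 (log2 fold change 0.64 ± 0.11), Il10 and Areg, of which Il10 and Areg are named after their values were seen. The list as a whole did not pass camera, a competitive gene set test (adjusted p = 0.480, and adjusted p = 0.632 with an estimated correlation). Its median log2 fold change was 0.29 and its mean -0.38.

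Among 17 measured genes for chemokines, chitinases, mucins and other effectors of type 2 airway inflammation, 4 rose and 5 fell, as they did when adjusted over the list alone. Ccl22, a chemokine for Th2 and regulatory T cells, fell by 2.01 ± 0.33 on the log2 scale, and the chitinase-like gene Chil4 fell by 1.97 ± 0.34. The other fallers were Clca1, Muc5b and Mrc1. The risers were Arg1 (1.03 ± 0.25), Ccl8 (0.98 ± 0.20), Ccl7 (0.50 ± 0.11) and Chil3 (0.36 ± 0.10). Both of these sets are named after their values were seen. The camera test gave an adjusted p of 0.924, with a median log2 fold change of 0.097 and a mean of -0.42. Of 17 measured ILC2 markers 1 rose and 4 fell, also when adjusted over the list alone. Bcl11b (-1.55 ± 0.13), Ccr8 (-1.40 ± 0.16), Gata3 and Ptpn13 were lower and Id2 was higher, the last pair named after their values were seen. Bcl11b, Gata3 and Ccr8 are also expressed by T cells, several of whose markers fell as well. The ILC2 list did not pass camera (adjusted p = 0.106) and passed fry, downward (adjusted p = 0.0298). Leaving out any of VE-1, VE-2 and VE-3 ended the call of Il5 (adjusted p up to 0.0554), and leaving out any library but Aalter-1 ended that of Il13 (up to 0.0748), as did limma-voom (0.0523). Gata3 passed in all 6 such fits, with an adjusted p of at most 0.0461.

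**Figure D2:**
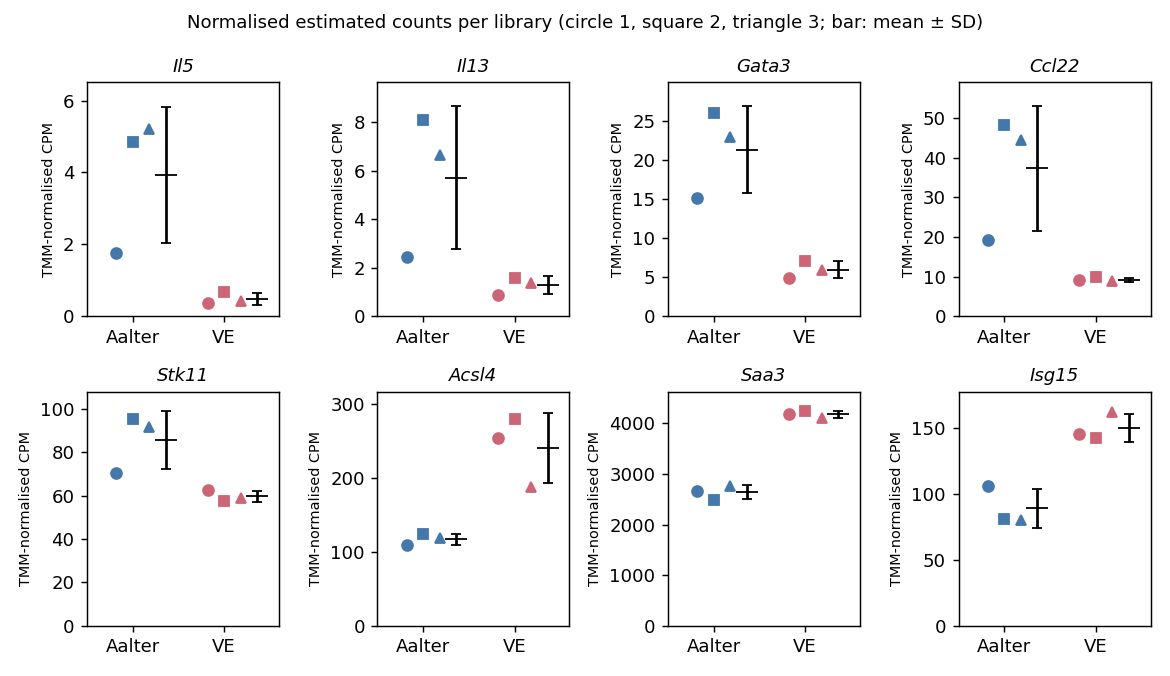
TMM-normalised CPM of 8 named genes in each library, with the mean and SD (n = 3) in black. Il5, Il13, Gata3, Ccl22 and Stk11 are lower in all 3 VE libraries than in any Aalter library, and Acsl4, Saa3 and Isg15 are higher. Il5 in Aalter-1 is 1.77 CPM, below Aalter-2 and Aalter-3.

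Stk11, the gene of LKB1, was lower in VE, at 59.7 ± 2.56 CPM against 85.8 ± 13.3 CPM in Aalter. Its log2 fold change was -0.52 ± 0.13 with an adjusted p of 0.0223. Stk11 (ENSMUSG00000003068) spans 80115803 to 80130682 on chromosome 10. Of 27 measured genes of LKB1, the energy-sensing kinase AMPK and their targets, 0 rose, 11 fell and 16 did not pass, and 12 fell when adjusted over the list alone. The smallest p-values were those of Tsc1, which restrains the growth kinase mTOR (-1.14 ± 0.12), the autophagy kinase gene Ulk1 (-0.93 ± 0.13), Rptor, a partner of mTOR (-1.21 ± 0.19), and the kinase gene Sik3 (-1.20 ± 0.19). The list passed camera with an adjusted p of 0.0137, and had an adjusted p of 0.598 with an estimated correlation. Genes that fell in VE were richer in GC and had longer transcripts than genes that rose, and with both trends removed, a setting added after seeing the data, 6 members fell, camera gave 0.155 and Stk11 was at 0.052 (adjusted p = 0.684). There Ulk1 was at -0.27 and did not pass (adjusted p = 0.0859), while Tsc1 (-0.70), Rptor (-0.54) and Sik3 (-0.66) passed with smaller falls. The call of Stk11 was also lost in 5 of the 6 fits without a library, all but that without Aalter-1, with an adjusted p of up to 0.0953. Its log2 fold change lay between -0.64 and -0.44 over the 6 fits, and those 5 fits lost most calls over all genes, as given below.

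Genes that promote ferroptosis moved both ways. Acsl4, which loads membrane lipids with polyunsaturated fatty acids, rose from 117 ± 7.45 CPM in Aalter to 240 ± 47.4 CPM in VE (log2 fold change 1.04 ± 0.16, adjusted p = 0.00752). Acsl4 (ENSMUSG00000031278) lies on chromosome X from 142317993 to 142390535. Trp53, the gene of the p53 tumour suppressor, fell by 2.14 ± 0.36 on the log2 scale (adjusted p = 0.0107). Of the 22 measured members 7 rose and 3 fell, also when adjusted over the list alone, and camera gave an adjusted p of 0.751. The list's median log2 fold change was -0.086 and its mean -0.13, while the test leaned upward. The call of Acsl4 was lost without VE-2 (adjusted p = 0.0514) and, in a fit added after seeing the data, without both Aalter-1 and VE-1 (0.0619).

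Among 23 measured genes that protect from ferroptosis, 5 rose and 1 fell, as they did when adjusted over the list alone. Fth1, the ferritin heavy chain, rose from 9504 ± 471 to 14283 ± 695 CPM (log2 fold change 0.59 ± 0.11), and Gclc, which makes glutathione's precursor, fell by 0.71 ± 0.13. Gpx4, the peroxidase that reduces lipid peroxides, did not pass (-0.27 ± 0.25, adjusted p = 0.437), nor did the cystine transporter gene Slc7a11 (0.57 ± 0.21, adjusted p = 0.0699). Slc7a11 did pass without Aalter-1 (0.87, adjusted p = 4.2e-07), with DESeq2 (0.0246) and with the GC content and length trends removed (0.0279), and its adjusted p over all alternatives reached 0.208. The list did not pass camera (adjusted p = 0.329) and passed fry, upward (adjusted p = 0.0248). Of 26 targets of the antioxidant factor NRF2, 6 rose, among them the peroxiredoxin gene Prdx5 (0.71 ± 0.12), and 2 fell, the same numbers as when adjusted over the list alone (camera adjusted p = 0.208). Of 9 genes for handling vitamin E, 0 rose and 2 fell, also when adjusted over the list alone. These were the lipid exporter gene Abcg1 (-0.99 ± 0.11) and the lipoprotein receptor gene Scarb1 (-0.83 ± 0.17), and camera gave an adjusted p of 0.440. Cyp3a11 (0.27 ± 1.70) and Cyp3a13 (0.28 ± 0.91) of this list are among the 216 trace genes of Aalter-1 and VE-1 described below. Their spread leaves a change in either direction open, and both are named after their values were seen. In lipid synthesis and storage 2 of 20 genes rose and 7 fell, again also when adjusted over the list alone. The smallest p-values were those of Lpin1 (-1.81 ± 0.22) and the master regulator Srebf1 (-1.73 ± 0.22, and -1.11 with the GC content and length trends removed), with a camera adjusted p of 0.268.

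Genes of acute inflammation, the interferon response, neutrophils and monocytes were higher in VE. Of 22 measured genes of acute inflammation 14 rose and 0 fell, against 17 and 1 when adjusted over the list alone. Saa3, an acute-phase protein gene, rose from 2640 ± 142 to 4181 ± 67.6 CPM (0.66 ± 0.10), with Il6, the monocyte chemokine gene Ccl2 (0.63 ± 0.11) and the iron-binding lipocalin gene Lcn2 (0.78 ± 0.15). Of 24 interferon-response genes 12 rose and 0 fell, against 21 and 1 when adjusted over the list alone, with the smallest p-values in Isg15 (0.75 ± 0.13), Oas3 (0.73 ± 0.17), Zbp1 (0.90 ± 0.21) and Irgm1 (1.10 ± 0.26). Neutrophil markers gave 11 risers and 0 fallers among 15, or 12 and 0 when adjusted over the list alone, with the smallest p-values in Stfa2l1 (0.85 ± 0.11), Ngp (0.74 ± 0.14), Mmp9 (0.59 ± 0.12) and Mmp8 (0.79 ± 0.16). In the list of interstitial macrophages and monocytes 10 of 14 rose and 1 fell, or 13 and 1 when adjusted over the list alone. Ly6c2 (0.86 ± 0.16), Ccr2 (0.74 ± 0.16) and Cd14 (0.87 ± 0.20) rose, and the fractalkine receptor gene Cx3cr1 fell by 0.97 ± 0.17. Camera gave these lists adjusted p-values of 2.55e-05, 3.39e-06, 0.000123 and 0.000267 in that order, each with an adjusted p of 0.598 with an estimated correlation. Fry gave them 0.0136, 0.0767, 0.0298 and 0.0767, so the interferon and the macrophage and monocyte lists did not pass fry. With library size alone as the scaling 9, 3, 8 and 4 members rose and the 4 lists still passed camera. With the GC content and length trends removed the neutrophil list no longer passed (adjusted p = 0.143) and Stfa2l1, of a family of near-identical genes, was at -0.68 (adjusted p = 0.0798), and Il6 (0.27, adjusted p = 0.0630) and Ccl2 (0.16, adjusted p = 0.233) did not pass either.

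Most B, T and natural killer cell markers that passed the test were lower in VE. Of 13 B cell markers 0 rose and 9 fell, or 0 and 10 when adjusted over the list alone. The IgE receptor gene Fcer2a fell by 2.80 ± 0.39, the B lineage factor gene Pax5 by 1.496 ± 0.15, Ebf1 by 1.17 ± 0.18 and Blk by 0.94 ± 0.14 on the log2 scale (camera adjusted p = 0.000525, and adjusted p = 0.598 with an estimated correlation). Of 17 T cell markers 2 rose and 9 fell, also when adjusted over the list alone, with Cd3e (-0.86 ± 0.13) among the fallers. The risers were Cd3g (0.31 ± 0.094) and Ctla4 (0.67 ± 0.18), while Cd3d did not pass (0.11 ± 0.10, adjusted p = 0.440). These were named after their values were seen. Of 12 natural killer cell markers 1 rose and 8 fell, or 3 and 8 when adjusted over the list alone, with the smallest p-values in Eomes (-2.61 ± 0.16, adjusted p = 0.00144) and Ncr1 (-1.86 ± 0.30). The T and natural killer cell lists did not pass camera (adjusted p = 0.0729 for both). Dendritic cell markers gave 0 risers and 4 fallers among 11, also when adjusted over the list alone, with the smallest p-values in Ccr7 (-2.41 ± 0.26) and Zbtb46 (-2.33 ± 0.37) and a camera adjusted p of 0.116.

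Plasma cell markers were higher in VE in all 16 measured members, or 15 when scaled by library size alone, but 3 rose by the test, or 1 when adjusted over the list alone. Tnfrsf17, a survival receptor of plasma cells, rose by 1.16 ± 0.25, Xbp1 by 0.75 ± 0.21 and Txndc5 by 0.84 ± 0.26 on the log2 scale. Each passed in 1 of the 6 fits that leave out a library. Tnfrsf17 did not pass with the GC content and length trends removed (0.75, adjusted p = 0.0561), nor did Xbp1 and Txndc5 with the replicate block. Igkc, the kappa light chain, was at 3366 ± 2879 CPM in Aalter and 12782 ± 4527 CPM in VE, a log2 fold change of 1.92, and did not pass (adjusted p = 0.0658). It did pass without Aalter-1 (2.91, adjusted p = 0.00778), with DESeq2 (0.0350) and with limma-voom, and not with the GC content and length trends removed (1.13, adjusted p = 0.0577), and its adjusted p over all alternatives reached 0.166. Immunoglobulin genes made up 2.37%, 0.534% and 0.542% of counts in Aalter-1 to Aalter-3 and 2.68%, 3.10% and 5.28% in VE-1 to VE-3. The list's camera adjusted p was 0.000107, and its adjusted p was 0.598 with an estimated correlation.

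Mast cell and basophil markers went both ways, with 4 of 9 risen and 2 fallen, also when adjusted over the list alone. The mast cell protease gene Cma1 fell by 2.09 ± 0.29 and the stem cell factor receptor gene Kit by 0.56 ± 0.13 on the log2 scale (camera adjusted p = 0.444). Among 10 eosinophil markers 1 rose and 2 fell, also when adjusted over the list alone, and both fallers, Ear1 (-1.40 ± 0.35) and Ear2 (-0.93 ± 0.27), belong to a multigene family whose counts are uncertain, and were at -2.32 and -1.84 with the GC content and length trends removed. That list had a camera adjusted p of 0.878, a median of 0.14 and a mean of -0.073.

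Among alveolar macrophage markers 1 of 13 rose and 6 fell, also when adjusted over the list alone. The fallers included the integrin gene Itgax (-1.21 ± 0.24), Krt79 (-2.19 ± 0.46), Cidec (-2.12 ± 0.53) and Abcg1. In the club cell list 4 of 11 fell and 1 rose, also when adjusted over the list alone. Scgb1a1, the main secretory protein of club cells, fell from 273 ± 86.2 to 100.2 ± 10.2 CPM (-1.44 ± 0.24, and -2.59 with the GC content and length trends removed), with Cbr2 (-1.21 ± 0.20) and Bpifb1 (-2.12 ± 0.41). The riser was Hp, the acute-phase protein haptoglobin (0.75 ± 0.17). Both lists had a camera adjusted p of 0.0476, and adjusted p-values of 0.632 and 0.598 with an estimated correlation. Scaling by library size alone ended both calls (0.0786 and 0.102), as did a mean of at least 5 CPM (0.0926 for both).

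Of 6 red cell genes 0 rose and 5 fell, or 0 and 6 when adjusted over the list alone, among them Hba-a1 (-1.04 ± 0.18), Hba-a2 (-1.24 ± 0.22), Hbb-bs (-0.75 ± 0.19) and Hbb-bt (-0.78 ± 0.17), which are near-identical pairs whose counts could be split between copies. With the GC content and length trends removed Hba-a2, Hbb-bs and Hbb-bt fell further, by 1.83, 1.49 and 1.39. Of 18 genes of glycolysis 9 rose and 0 fell, or 11 and 0 when adjusted over the list alone, with the smallest p-values in Tpi1 (0.75 ± 0.14), Pgk1 (0.65 ± 0.13), Eno1 (0.51 ± 0.12) and Pfkfb3 (0.42 ± 0.098). Of 26 nuclear genes of oxidative phosphorylation 6 rose and 0 fell, or 4 and 0 when adjusted over the list alone, by small amounts: Sdhd by 0.45 ± 0.090, Sdhb by 0.40 ± 0.096, Cycs by 0.35 ± 0.087 and Atp5f1c by 0.30 ± 0.082. Camera gave adjusted p-values of 0.00649, 0.00538 and 0.0142 for these lists, each with an adjusted p of 0.598 with an estimated correlation. With library size alone 2 glycolysis genes rose, and 0 genes of oxidative phosphorylation rose and 1 fell. The oxidative phosphorylation list no longer passed with library size alone (0.125) or with GC content and length trends removed (0.772).

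**Figure D3:**
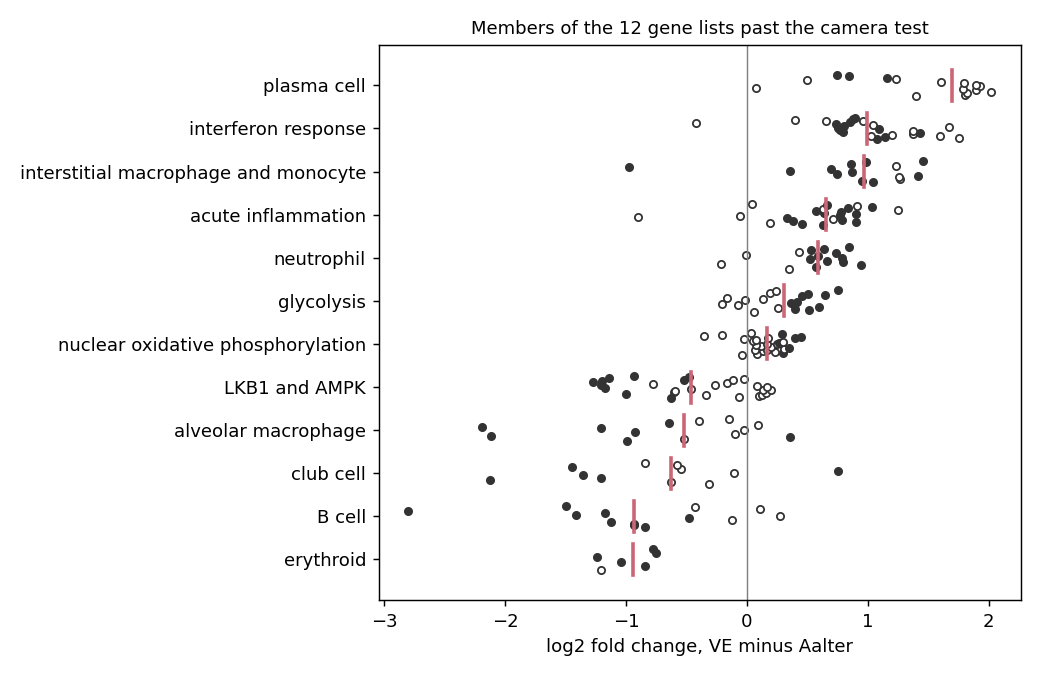
Log2 fold changes (VE minus Aalter) of the measured members of the 12 lists that passed camera with a preset correlation. Each point is a gene, filled where it passed edgeR's test, and red bars are list medians. Medians run from -0.94 in the erythroid list to 1.70 in the plasma cell list.

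The largest falls by the rule for named genes were in Kcnh4, Hivep3, Rnf157, Zhx2, Fam83g, Whrn, Cpne5 and Myc, with log2 fold changes from -5.04 to -3.99, and from -4.38 to -3.34 with the GC content and length trends removed. Myc, the growth-promoting transcription factor (ENSMUSG00000022346, chromosome 15 from 61985391 to 61990374), fell from 173 ± 111 CPM to 10.9 ± 1.81 CPM, a log2 fold change of -3.99 ± 0.71 with an adjusted p of 0.0166. In Aalter-1 Myc was at 45.5 CPM against 243 and 230 CPM in Aalter-2 and Aalter-3. Myc, Fam83g and Cpne5 each passed in 1 of the 6 fits that leave out a library, that without Aalter-1, with adjusted p up to 0.0734, 0.0982 and 0.0691. Hivep3 passed in 3, Kcnh4 and Zhx2 in 5, and Rnf157 and Whrn in all 6. Zhx2, a transcriptional repressor, fell from 189 ± 105 to 10.01 ± 1.30 CPM, and Rnf157, a ubiquitin ligase gene, from 83.8 ± 35.0 to 4.40 ± 0.628 CPM. The largest rises were smaller, with log2 fold changes from 1.56 to 2.08, in genes of at most 4.30 CPM in VE, among them Ugt1a6b, Psg16, Cstdc6, Ccdc62, Oosp1, Creg2 and Pycr1. Ugt1a6b, Psg16 and Cstdc6 belong to families of similar genes, so their counts are uncertain.

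Over the transcriptome, 4054 of 12551 tested genes passed an adjusted p of 0.05, of which 1612 were higher and 2442 lower in VE. At 2-fold or more, 207 were higher and 999 lower, against 974 and 1421 without Aalter-1. The groups did not overlap in 51.9% of tested genes, where chance gives 10%. With library size alone as the scaling 495 were higher and 3231 lower, with a median log2 fold change of -0.117 over all genes against 0.0228, and with the GC content and length trends removed 1690 were higher and 1598 lower. Leaving out Aalter-1 raised the total to 7213 genes, and leaving out Aalter-2, Aalter-3, VE-1, VE-2 or VE-3 lowered it to 921, 679, 481, 179 or 909. Of 89 genes past the threshold that the naming rule takes outright or from the lists described above, with the other lists not counted, 89 still passed without Aalter-1, and 45, 33, 23, 13 and 38 without Aalter-2, Aalter-3, VE-1, VE-2 and VE-3. With the GC content and length trends removed 77 did, and those that did not were Stk11, Ulk1, Il6, Ccl2, Stfa2l1, Tnfrsf17, Kit, Sdhd, Cycs, Atp5f1c, Oosp1 and Cstdc6.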

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

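The settings without Aalter-1 and VE-1, without immunoglobulin genes and with GC content and length trends removed were chosen after the data were seen. RLE scaling, DESeq2, limma-voom, no filter, a mean of at least 5 CPM and the fit without immunoglobulin genes gave between 3525 and 4505 genes past the threshold, against 4054. A 2-fold minimum left 1206 genes, 207 higher and 999 lower. Library size alone gave 495 higher genes, the fit without Aalter-1 and VE-1 gave 6963 genes with 3404 higher, and trends removed gave 1598 lower. Over the 6 fits that leave out a library, between 179 and 7213 genes passed, between 2 and 3561 higher and between 177 and 3652 lower, and the cause was not tested. The common biological coefficient of variation was 0.121 without Aalter-1 and between 0.217 and 0.250 in the others, against 0.210 with all libraries. The numbers of the libraries were not taken to pair them in the main test, since the labels give no pairing. The deviations of same-numbered libraries correlated at 0.299, 0.272 and 0.0532, against -0.289 to 0.171 for different numbers. These correlations alone leave a link between same-numbered libraries open. The shared trace transcripts given below, 216 genes for the libraries numbered 1 and 9 for those numbered 3, argue for a link there. Whether it is a shared batch was not tested, and the main test takes no account of it. With the number as a replicate block 3267 genes passed, 1193 higher and 2074 lower, and 14 lists passed. Of 89 named genes past the threshold, members of lists not described left aside, 89 passed with RLE, 77 with library size alone, 89 with DESeq2, 82 with limma-voom, 85 with no filter, 71 with a mean of at least 5 CPM (the others fell under it), 83 with the replicate block (not Cycs, Atp5f1c, Pycr1, Xbp1, Ear2 and Txndc5), 77 with trends removed, and from 13 without VE-2 to 89 without Aalter-1. Their direction held in all settings except Stfa2l1 (-0.68) and Stk11 (0.052) with trends removed, where Il4 (-0.37) and Il33 (-0.17), not past the threshold, also turned. Lists past camera numbered 9 to 17 over the other settings and 10 to 13 over the fits that leave out a library, against 12, and 0 with an estimated correlation. Lists that changed direction did not pass in the main setting. With trends removed they were mitochondrial-encoded genes, which then passed (adjusted p = 0.000288), type 2 cytokines and eosinophils (0.426 each), mast cells (0.963), ciliated cells (0.987) and replication histones (0.390). Without Aalter-1 and VE-1 they were ferroptosis-promoting and mitochondrial-encoded genes (0.902 each), eosinophils (0.632), ciliated cells (0.930), immediate early genes (0.391), endoplasmic reticulum stress (0.930) and replication histones (0.785). With a mean of at least 5 CPM they were eosinophils (0.528), type 2 alveolar cells (0.888) and endothelium (0.507), and with library size alone type 2 effectors (0.777). Leaving out Aalter-1 turned ferroptosis-promoting genes, eosinophils, ciliated cells, immediate early genes, endoplasmic reticulum stress and replication histones, and leaving out VE-3 turned skeletal muscle and adipocytes. Over the 6 fits that leave out a library, the adjusted p lay between 0.629 and 0.883 for ferroptosis-promoting genes, 0.624 and 0.966 for eosinophils, 0.570 and 0.925 for ciliated cells, 0.351 and 0.703 for immediate early genes, 0.359 and 0.983 for endoplasmic reticulum stress, 0.553 and 0.966 for replication histones, 0.674 and 0.996 for skeletal muscle, and 0.271 and 0.961 for adipocytes. The causes of these changes were not tested.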

Other observations

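The gene groups in the next paragraph were chosen only after the data were seen. So were the tests of a label swap, of a wrong label, of liver RNA and of agreement by chance. The tests of mixing, of GC content and length, of scaling and of other splits were set out before their results were seen. The preset rule for mixing asked for a share of moved genes in Aalter-1 no larger than in VE-3, which held (0.419% against 0.571%). The preset rule against scaling asked for a large excess of falls under both scalings, which also held. Conditions absent from these rules were then applied, and they leave both questions undecided for the reasons given below.

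Antigen presentation genes of MHC class II were lower in VE, with 0 of 9 measured members risen and 6 fallen. Cd74, the invariant chain, fell from 1435 ± 512 CPM to 557 ± 36.04 CPM (log2 fold change -1.37 ± 0.27), and their master regulator Ciita fell from 10.9 ± 0.633 to 4.02 ± 1.21 CPM (-1.43 ± 0.22). Of the B cell and dendritic cell markers above, 9 of 13 and 4 of 11 fell as well, and a change in cell content was not tested. Receptors for antibody constant regions and complement C1q moved the other way, with 5 of 9 risen and 0 fallen. The C1q genes are also in the list of interstitial macrophages and monocytes, where 10 of 14 rose, so these lists are not independent. Fcgr4 rose from 153 ± 18.8 to 253 ± 7.74 CPM (0.72 ± 0.11) and Fcgr2b, the inhibitory receptor, from 138 ± 44.9 to 268 ± 12.2 CPM (0.96 ± 0.21). Of 16 genes of ribosome biogenesis, with Myc among them, 0 rose and 7 fell, such as Rrp12 (-1.23 ± 0.18) and Nolc1 (-1.19 ± 0.29), while 22 cytosolic ribosomal protein genes had a median log2 fold change of -0.067. These lists were made after the values were seen, so no p-value is given for a list as a whole.

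Aalter-1 lay between the other Aalter libraries and VE. Over 734 genes that differed by at least 1.5 on the log2 scale, it stood at a median of 0.62 of the way from Aalter-2 and Aalter-3 to VE, with an interquartile range of 0.524 to 0.727 and medians of 0.605 for genes higher and 0.621 for genes lower in VE. A swap with a VE library is argued against, since the lowest VE score on the first component was 36.01 and no VE library was out of place. A VE library with a wrong label that varies as these 3 do is argued against too, since each VE library, placed against the mean of the other 2, had a median share of 0.989 to 0.991 and a lower quartile of at least 0.798. RNA of both groups in 1 library cannot be told apart from a sample with an in-between response. Of 1911 genes level in the other 5 libraries, 0.419% lay beyond 1.5-fold in Aalter-1, but the other libraries left out in a like way gave between 0.0461% and 0.606%, so this measure separates no library from the rest. A weaker or stronger response of this sample is untested.

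The libraries numbered 1 and those numbered 3 shared transcripts of other tissues. Aalter-1 and VE-1 shared 216 genes at over 1 CPM and over 2-fold above the other 4 libraries, Aalter-3 and VE-3 shared 9, among them the intestinal genes Reg3b (16.6 and 15.3 CPM) and Muc2, and Aalter-2 and VE-2 shared 1, the pigment cell gene Tyr (14.1 and 10.4 CPM). Pairs with different numbers shared at most 1 gene, which argues against agreement by chance for the libraries numbered 1 and, on fewer genes, for those numbered 3. Those numbered 2 cannot be told apart from it, because they too shared 1 gene. Liver RNA or reads in both libraries numbered 1 are a candidate source: all 24 hepatocyte genes were higher in both than in the other 4, the log2 ratio between the 2 libraries had an SD of 0.12, and Alb was at 629.5 and 729 CPM against 20.4 to 42.4 CPM elsewhere. Whether such traces entered at dissection, in the laboratory or between samples in sequencing was not tested, nor was a biological explanation, and without both libraries 6963 genes passed, 3998 of them among the 4054.

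Falls of 2-fold outnumbered rises, 999 to 207, and genes that fell were richer in GC (median 52.7%, against 47.2% in genes that rose) and longer (4454 against 2701 bases). A GC and length trend between libraries as the whole cause is argued against, since 816 of the 995 fallers with both values still passed in the same direction after its removal, with their median log2 fold change moving from -1.40 (SD 0.58) to -1.05 (SD 0.63), and falls of 2-fold still outnumbered rises, 550 to 248. It may account for part of the excess, as that removal also left 1598 lower genes against 1690 higher. The scaling cannot be told apart from other causes: the lowest ratio of 2-fold falls to rises under RLE or library size alone was 4.77, but RLE left the median log2 fold change of all genes at 0.0185 against 0.0228 and library size alone lowered it to -0.117, so neither could have removed an excess of falls. The size of the excess depends on the libraries and on the test: falls and rises of 2-fold numbered 1421 and 974 without Aalter-1, 1404 and 964 without Aalter-1 and VE-1, and 853 and 403 with limma-voom, while leaving out Aalter-2, Aalter-3, VE-1, VE-2 or VE-3 gave 463, 418, 353, 157 or 492 falls and at most 16 rises. A difference between the Aalter and VE groups stays open as well.

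Of the 10 ways to split the 6 libraries into groups of 3, only the real split (1 of 10) gave as many as 4054 genes, and the highest of the other 9 gave 0 by edgeR, with up to 985 at an unadjusted p under 0.05. So few splits allow no share under 0.05.

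Y-linked genes were lower in Aalter-2 and Aalter-3 than elsewhere: Ddx3y was at 107, 56.4 and 55.7 CPM in Aalter-1 to Aalter-3 and at 115, 117 and 135 CPM in VE-1 to VE-3, and Eif2s3y at 43.2, 20.5, 23.4, 48.1, 52.4 and 59.6 CPM in that order. The ratio of Ddx3y to the X-linked Ddx3x was 0.0959, 0.0572, 0.0578, 0.0998, 0.103 and 0.125 in that order. The labels do not give the sex of the animals, so a difference in sex make-up between the groups cannot be told apart from other causes.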
